A study of Rattus norvegicus with 6 samples.

How the data were processed

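Gene expression was measured on 6 two-colour Agilent rat arrays of 44290 features each, 2 for each of striatum, salivary glands and peripheral leukocytes. Per the labels, tickled RNA was in Cy5 on every array and RNA of the comparator, no stimulus or light touch, in Cy3, with 500 ng of input RNA. The values used are log2 ratios as deposited by the authors, 1 per feature and array, taken as tickled over comparator. The submitters' processing notes name Agilent Feature Extraction 9.1; the normalization, the rule for blank values and the log base are not given in the sources used here. Base 10 is excluded, since the largest absolute value, 7.75, would be a ratio of 56500000, against 216 in base 2. Natural logs are not excluded. The direction comes from the dyes in the labels and is not stated with the values. Channel intensities were not used here.

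Features were joined to gene symbols through the platform annotation and the RefSeq gene table of assembly GRCr8: 23535 features carried 1 symbol, 48 several and 20707 none. Entrez identifiers matched for 23488 features and 1 symbol was updated. Only features with 1 symbol entered gene values, giving 14871 symbols; 12768 features had no value on any array and 10744 had one on all. A gene's value is the median over its probes. Features with several symbols or none were left out of the comparisons, and unnamed features were searched separately.

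With 1 array per comparison, genes were counted by size (2-fold) without a test. A sample stood apart when it lay 2-fold from both other samples of its tissue, with light touch against no stimulus taken as the difference of the 2 arrays. Whether the same tickled extract is on both arrays of a tissue is not given in the sources used here; the difference of the arrays, the counts per sample and the simulations take it to be so. Since tickled RNA is on both arrays of a tissue, their correlation across genes was set beside 100 simulations of 3 exchangeable samples. The 45 gene lists comprised 26 for striatum, 23 for salivary glands and 18 for leukocytes, some shared. Each list with 3 or more genes valued on both arrays of a tissue has its median per array over those genes and the percentile of that median among 10000 random lists matched on list size and number of probes; random lists were not matched on expression. Medians over every gene measured on an array are given where they differ in sign or much in size, and for the mucous acinar markers, of which 2 were valued on both arrays. Medians outside the central 95% on both arrays the same way were found for 7 lists in striatum, 2 in salivary glands and 0 in leukocytes. Since both arrays carry tickled RNA, the count was also made for each of the 3 samples, with random lists drawn once for both arrays; this gave 6, 2 and 0 lists for the tickled sample, and random lists gave means of 0.202, 0.157 and 0.112. Random lists hold unrelated genes, whereas genes of a list can vary together in any sample.

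Genes were named by a rule per tissue: the 10 genes each way with the largest smaller-of-both absolute ratio among genes of the same sign on both arrays; the 5 each way by size on a single array that these leave out; the 5 each way that differ most between the arrays; list members 1.5-fold apart the same way on both arrays; and up to 4 members of each list described. Named genes needed a symbol other than a locus number, values on both arrays, and probes that all share the sign of the gene's median. The text gives part of these genes and leaves out most olfactory receptor genes. Named outside the rule, after their values were seen, were Lamp5, Nrgn, Rtn4rl2, Klk9, Scnn1g, Slc12a2, Pip, Car6, Lpo, Gcnt3 and Prpmp5. The lists, the rule, the counts and the alternatives were set before the data were examined, except reading the values as natural logs, the list counts per sample and the explanation tests, which were added later.

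The procedure was tested on simulated data with normal noise and 200 genes changed 4-fold in the tickled sample: 100% of them and 0 unchanged genes were counted in each tissue. Separate simulations took 3 exchangeable samples with no effect planted. Their values were resampled from both real arrays of a tissue together, wide tails included, so a deviation of any real sample enters every simulated one. A mean of 1.97 genes in striatum, 38.9 in salivary glands and 10.5 in leukocytes were then 2-fold apart on both arrays. In the simulation with normal noise, a planted list of 15 genes changed 4-fold reached percentile 100, an outcome set by its size. There, 3.5%, 6% and 7% of null lists fell outside the central 95% in simulated striatum, salivary glands and leukocytes. These rates used fewer random lists than the main comparison and do not cover the wide tails of the real arrays.

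Alternatives were centring and scaling of the arrays, the mean or the smallest probe of a gene, genes with 2 or more agreeing probes, subtraction of the other tissues' median per gene, leaving out genes alike in the other tissues, fold limits of 1.5 and 3, natural logs, and a filter on values of exactly 0, of which there were 0. The base 10 reading and a turned sign were not run, because the values exclude the first and no tissue met the condition set for the other. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with random seed 1.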

Results

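Gene expression was compared in striatum, salivary glands and peripheral leukocytes of male Wistar rats, an outbred laboratory strain, that had been tickled, touched lightly or given no stimulus. Tickling by hand served as a mimic of rough-and-tumble play and evokes 50 kHz ultrasonic calls, which are read as a sign of positive emotion in rats; light touch was the control for handling. Animals were housed singly from 21 days of age, stimulated once each weekday for 4 weeks in cycles of 15 s of rest and 15 s of stimulation, and were 60 days old at sampling. Each of the 6 samples is 1 two-colour array that sets tickled RNA (Cy5) against RNA of 1 comparator (Cy3) from the same tissue. An array is called here by its tissue and comparator: the no-stimulus array and the light-touch array.

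There is 1 array per comparison, with no replicate and no dye swap, so no p-value, standard deviation or count of significant genes is given and the number of arrays limits the precision. Per the labels each condition had 4 animals, and whether an array holds their pool or 1 animal is not given in the sources used here. Nor is it given whether both arrays of a tissue carry the same tickled extract; statements on light touch against no stimulus, and on a sample apart from both others, hold only if they do. The labels also name hypothalamus as the extracted tissue of every sample, beside the tissues used here. Log2 ratios are tickled over comparator, read in base 2, which the values do not settle against the natural log; under natural logs each value would be 1.44 times as large. The only error at hand is the disagreement between probes of a gene, with a median standard deviation of 0.12 and 0.09 on the striatal no-stimulus and light-touch arrays, 0.10 and 0.09 on the salivary arrays, and 0.15 and 0.20 on the leukocyte arrays. Genes with a value numbered 10922 and 10835 in striatum, 10522 and 10716 in salivary glands, and 6316 and 6182 in leukocytes, in the same order. The array medians over all features were 0.001 and 0.003 in striatum, 0.002 and 0.004 in salivary glands, and -0.001 and 0.014 in leukocytes.

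The striatum comparison asks which genes of this part of the forebrain, which takes part in reward and movement, differ after tickling. Genes of excitatory cortical neurons were lower in the tickled sample than in both comparators. Slc17a7, the vesicular glutamate transporter of cortical neurons, had log2 ratios of -1.20 over no stimulus and -1.13 over light touch, and Tbr1, a transcription factor of cortical glutamatergic neurons, had -1.26 and -0.96. Bdnf, a neurotrophin, had -1.31 and -0.99, and the neuropeptide gene Cck had -1.06 and -1.01. The genes highest in tickled striatum on both arrays were smaller in size: Avp, which encodes vasopressin, had 0.78 and 0.73, and the aldo-keto reductase gene Akr1c13 had 0.77 and 0.92, and its relative Akr1c19 had 0.74 and 0.76. These paralogs are close in sequence, so their probes may not tell them apart.

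Of the genes fixed as cortical neuron markers, 10 were measured on both striatal arrays. Their median was -0.57 over no stimulus and -0.61 over light touch, at percentile 0 of 10000 random lists on both arrays, and 4 members were 1.5-fold or more lower on both arrays: Slc17a7, Tbr1, Neurod6 (-0.89 and -0.82) and Nrn1 (-0.78 and -0.99). With the other tissues' median subtracted, the median over light touch was -0.32 over 6 markers. The rest, Tbr1 among them, fell out for lack of values in the other tissues, so the change mixes their loss with the subtraction. Members were not alike, since Lamp5 (0.10 and -0.02), Nrgn (0.09 and -0.01) and Rtn4rl2 (0.04 and -0.03) lay near 0. Medium spiny neurons are the main neurons of the striatum, and none of their 16 measured markers passed 1.5-fold on either array; their median was -0.10 and -0.00, with Ppp1r1b (DARPP-32) at -0.42 and -0.15 and Penk at -0.14 and -0.15.

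**Figure D1:**
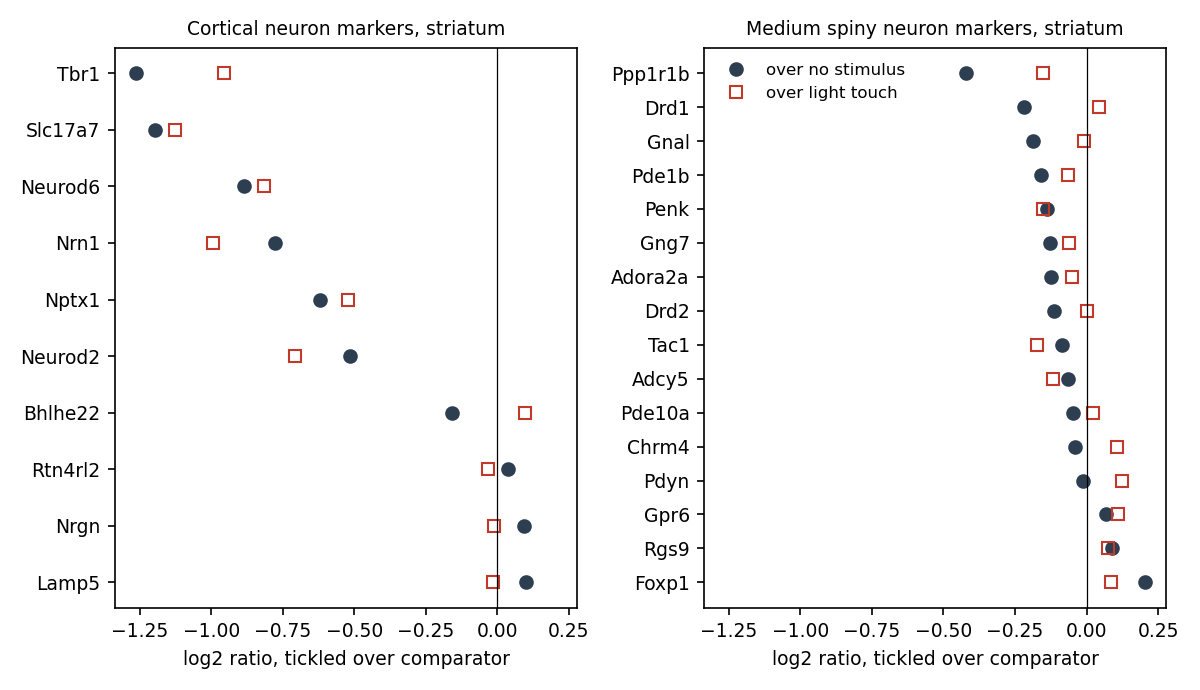
Log2 ratios of tickled over no stimulus (filled circles) and over light touch (open squares) for each measured cortical neuron marker and medium spiny neuron marker in striatum. Cortical markers spread from -1.26 for Tbr1 to 0.10 for Lamp5 over no stimulus, with 6 of them below 0 on both arrays, while the medium spiny markers had medians of -0.10 and -0.00.

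Of the signalling lists of the striatum, the serotonin and adrenergic receptors and the neurotrophic genes lay outside the central 95% of random lists on both arrays, in a sample whose cortical markers were lower too. Serotonin and adrenergic receptors had a median of -0.18 over no stimulus and -0.10 over light touch (percentiles 0.10 and 0.46), with 12 of 14 below 0 on both arrays: Adra1d, the alpha-1D adrenergic receptor, had -0.83 and -1.54, Htr1a had -0.52 and -0.84, and Htr2a had -0.44 and -0.31. Among 16 immediate early genes, which neuronal activity induces, the median was -0.12 and -0.06 (percentiles 4.36 and 6.18). Nr4a2 was 1.5-fold lower on both arrays (-0.82 and -0.70), and the synaptic scaffold gene Homer1 had -0.58 and -0.59. The 20 opioid and neuropeptide genes had medians of -0.10 and -0.01 (percentiles 5.84 and 41.9), with Avp higher and Cck and Vip (-0.76 and -1.18) lower on both arrays. Neurotrophic factors and receptors had medians of 0.19 and 0.09 (percentiles 99.98 and 98.4), yet their members went both ways: Ngfr had 0.53 and 0.61, Bdnf was lower, and Nptx2 had -0.55 and -0.58. Over the 3 members with agreeing probes their medians were -0.55 and -0.58. The 9 dopamine genes had medians of 0.04 and 0.08 (percentiles 81.2 and 94.3), with Th, the rate-limiting enzyme of dopamine synthesis, at 0.50 and 0.23, and none was 1.5-fold apart on either array. Medians were -0.06 and -0.02 for 21 glutamate and GABA genes (Grm5 at -0.40 and -0.09; percentiles 19.1 and 25.0) and 0.08 and 0.04 for 8 interneuron markers (Slc5a7 at 0.17 and 0.43; percentiles 91.1 and 78.3).

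Among the following markers of neighbouring regions and other cells, only the hypothalamus list lay outside the central 95% the same way on both arrays. No thalamus and septum, oligodendrocyte, astrocyte, microglia or vascular marker valued on both arrays was 1.5-fold apart on either. Hypothalamus markers had medians of 0.12 and 0.15 (percentiles 98.5 and 99.9), with 7 of 10 above 0 on both arrays, among them Avp and Hdc (0.21 and 0.69). Oxt, which encodes oxytocin, was 2.12-fold higher over no stimulus (1.08) and 0.15 over light touch. Thalamus and septum markers had medians of 0.14 and -0.11. Over no stimulus, oligodendrocyte markers had a median of 0.22 (Opalin 0.30) and astrocyte markers 0.23 (Gfap 0.30), at percentiles 99.99 and 99.98, against 0.06 and 0.04 over light touch. The medians of microglia markers were 0.11 and 0.03, with Cd68 at 0.13 and 0.30, and those of vascular markers were 0.10 and 0.02, with Abcb1a at 0.34 and 0.27. Choroid plexus markers had medians of 0.07 and 0.23 over 5 genes (0.33 over the 6 measured on the light-touch array), with Folr1 at 0.28 and 0.61 and Igf2 at 0.60 and 0.23.

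Interferon-stimulated genes were slightly higher in tickled striatum on both arrays, with medians of 0.21 and 0.12 over 16 genes (percentiles 100 and 99.96) and with Ifit3 at 0.63 and 0.55 and Usp18 at 0.56 and 0.39. Cell cycle genes had medians of 0.11 and 0.21 (percentiles 99.6 and 100), with Cdk1 at 0.28 and 0.93 and Top2a at 0.32 and 0.88. Aspm, a mitotic spindle gene, was 2.85-fold higher over light touch (1.51) and 0.35 over no stimulus. Glucocorticoid-responsive genes had medians of 0.10 and 0.08 (percentiles 98.4 and 97.8), with Sult1a1 at 0.43 and 0.29, but -0.08 over no stimulus with the other tissues' median subtracted. Erythroid markers had -0.14 and -0.10 (Hbb -0.65 and -0.34), heat shock genes -0.08 and -0.07 (Hspb1 -0.43 and -0.32), and MHC class II genes -0.03 and -0.10 (Cd74 -0.03 and -0.41). Clock genes had -0.08 and 0.05 (Bmal1 -0.18 and -0.35), ribosomal protein genes 0.05 and 0.00, oxidative phosphorylation genes 0.04 and -0.06, and reference genes -0.07 and -0.03; no member of the last 3 lists was 1.5-fold apart on either array. That subtraction turned the sign over light touch for the neurotrophic, choroid plexus, erythroid, heat shock and oxidative phosphorylation lists, and over no stimulus for thalamus and septum markers (-0.15).

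Other striatal genes differed on 1 array more than on the other. Tjp1, which encodes the tight junction protein ZO-1, was 3.17-fold higher in tickled than in the no-stimulus sample, with its 4 probes between 1.27 and 2.01, but had -0.33 over light touch, a 4.00-fold difference between the arrays. Hpgd, a prostaglandin-degrading enzyme, had 1.40 over no stimulus and 0.43 over light touch, Ghrl (ghrelin) had 1.06 and 0.43, and the lens galectin-related gene Grifin had 1.05 and -0.87. Lower over no stimulus were Cntfr, a receptor of ciliary neurotrophic factor (-1.42, and -0.43 over light touch), and Cdon (-1.16 and -0.16). On the light-touch array, Ect2 was higher (1.29, and 0.48 over no stimulus) while the olfactory receptor gene Or6c6i (-1.58, and 0.24 over no stimulus) and Trim54 (-1.09, and 0.22 over no stimulus) were lower. The nuclear lamina gene Lmnb1 differed most the other way between arrays, at 0.97 over light touch and -0.39 over no stimulus. The rule also named Mlf1, Apobec1, Cln6, Lyve1, Tsnaxip1, Dnase2b and Kif22 as higher on both arrays, and Cbln2, Atoh7, Rspo2, Kcnj6 and the splicing factor gene Prpf31 as lower on both, the last with -1.57 and -1.35 on a single probe.

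By count, 5 striatal genes were 2-fold or more higher and 10 lower in tickled than in the no-stimulus sample, and 9 were higher and 9 lower than in the light-touch sample. In both arrays, 0 genes were 2-fold higher and 3 were lower, namely Prpf31, Slc17a7 and Cck. With the other tissues' median subtracted, 10 were higher and 4 lower in both arrays. The subtraction takes the same number from both arrays and so adds a shared part to both. Deposited values over the same 9507 genes gave 3. On single arrays that subtraction gave 18 higher and 13 lower over no stimulus, and 25 higher and 9 lower over light touch. Scaling to 1 spread gave 8 and 52 genes on the 2 arrays. As deposited, the 2-fold measure put the no-stimulus sample apart from both others for 2 genes and the light-touch sample for 3. In simulation, exchangeable samples gave a mean of 1.97 and at most 5. At 1.5-fold, the tickled, no-stimulus and light-touch samples stood apart for 46, 24 and 27 genes. Of the striatal lists, 6 put the tickled sample apart when random lists were drawn once for both arrays, 4 the no-stimulus sample and 2 the light-touch sample. A dye bias of probes has the same sign on both arrays, so it can raise the gene and list counts of the tickled sample. It cancels in light touch against no stimulus, so the counts of the 3 samples are not fully alike. The simulation held no dye bias and counted at 2-fold only. The 2 arrays correlated across 10706 genes with Pearson r = 0.56 and Spearman rho = 0.54 (covariance 0.018). Simulation of 3 exchangeable samples, 1 of them on both arrays, gave r = 0.50, rho = 0.47 and a covariance of 0.017, and genes are not independent replicates. In any tissue such a simulation gives r near 0.50 by construction, and its covariance follows from the variances of the arrays. These simulated values are a reference point and no test.

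The salivary gland comparison asks about an organ under autonomic control. Here the widest differences were on the no-stimulus array. Tissue kallikreins, serine proteases secreted by the granular ducts of the rat submandibular gland, were higher in tickled than in no-stimulus glands: Klk1c9 by 13.2-fold (3.73), Klk1c2 by 12.3-fold (3.62), Klk1c12 by 8.48-fold (3.08) and Klk1 by 3.68-fold (1.88). Over light touch the same genes had -0.19, -0.26, -0.23 and -0.30. Smr3b, which encodes a prohormone, had 3.03 over no stimulus and 0.12 over light touch, and Egf, the epidermal growth factor gene, had 2.14 and -0.14.

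Of 9 tissue kallikreins measured on both arrays, 8 were 1.5-fold or more higher over no stimulus and 0 over light touch. The list's medians were 2.15 (percentile 100) and -0.19 (percentile 0.20), and Klk9 alone lay below 0 on both (-0.24 and -0.17). The Klk1 genes are near-identical paralogs, so signal of 1 member can reach the probes of another, and the number of members that differ is uncertain. Kallikreins are also the family that the study is known for reporting from these glands, so the list is not independent evidence of its direction. Granular duct growth factors and peptides had medians of 0.63 and 0.11 over 7 genes (percentiles 100 and 96.3), with 4 of them 1.5-fold higher over no stimulus, including Smr3a (0.82 and 0.50). The first median was 0.05 over the 4 genes left when the other tissues' median was subtracted. The genes lost had too few values in the other tissues, so the change mixes their loss with the subtraction. Salivary ion and water transport genes had medians of 0.40 and -0.03 over 13 genes (percentiles 100 and 22.9). Scnn1g, a sodium channel subunit of ducts, had 1.05 and -0.03, the cotransporter gene Slc12a2 had 0.90 and -0.03, and the water channel gene Aqp1 had 0.60 and 0.44.

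**Figure D2:**
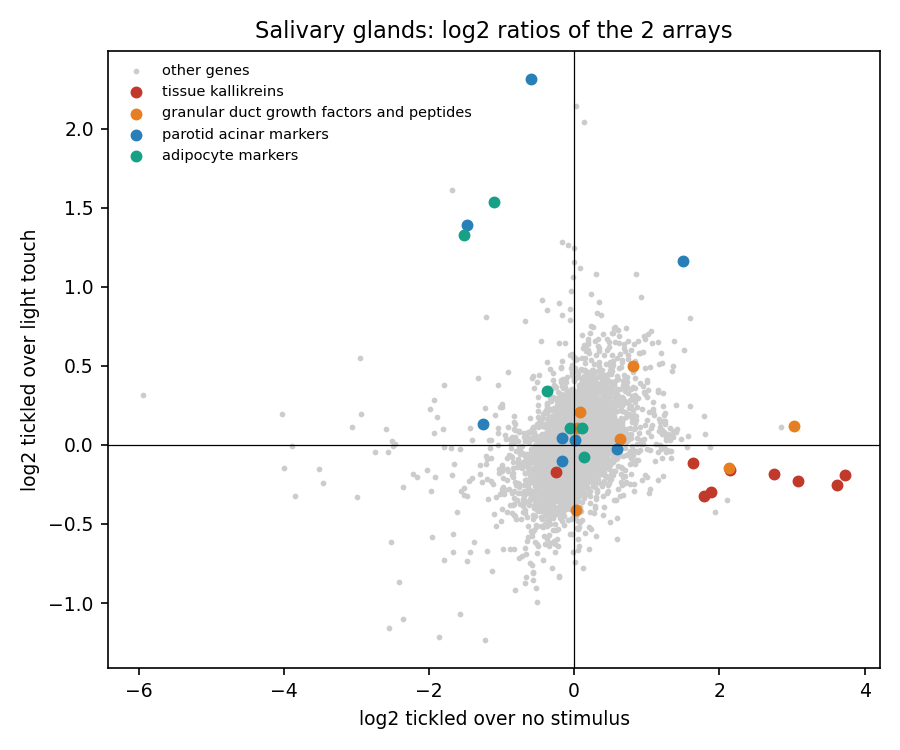
Each point is a gene measured on both salivary arrays, with the log2 ratio of tickled over no stimulus on the horizontal axis and of tickled over light touch on the vertical axis; coloured points belong to the lists named. Of the 9 kallikreins, 8 lie far to the right and slightly below 0 (medians 2.15 and -0.19), and Amy1, Adipoq and Retn lie to the upper left.

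Another set of gland genes went the other way on the no-stimulus array. Bpifa2f, of the family of secreted BPI-fold proteins, was 61.1-fold lower in tickled than in no-stimulus glands (-5.93) and had 0.32 over light touch; Csap1, the gene of a common salivary protein, had -4.03 and 0.19, Lman1l had -3.99 and -0.15, Bpifb2 had -3.88 and -0.01, and Cgref1 had -3.85 and -0.32. Among mucous acinar markers, Creb3l1 had -1.30 and -0.12 and Spdef was lower over no stimulus too. Gcnt3, a mucin-type glycosyltransferase gene, named here after its values were seen, had -4.11 over no stimulus and no value on the other array. Secreted salivary proteins therefore split, with 6 of 18 1.5-fold higher and 4 lower over no stimulus (medians 0.17 and 0.04, percentiles 99.8 and 88.0): Cyss (cystatin S) had 2.11 and -0.35, Pip had 1.87 and -0.01, and Dnase1 had -1.26 and 0.13. Cell cycle genes had a median of -0.44 over no stimulus (percentile 0), with Ube2c at -0.84 and Plk1 at -0.51, against -0.03 over light touch.

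Several parotid and fat genes were lower over no stimulus and higher over light touch. Amy1, which encodes amylase, had -1.47 over no stimulus and 1.39 over light touch, Bpifa2, the parotid secretory protein gene, had -0.59 and 2.31, Adipoq (adiponectin) had -1.52 and 1.33, Retn (resistin) had -1.11 and 1.53, and Car3, a carbonic anhydrase gene abundant in fat, had -1.68 and 1.61. Other parotid acinar markers did not follow, with Car6 at 0.59 and -0.03, and Lpo at 0.01 and 0.03. The 8 parotid markers had medians of -0.17 and 0.09 (percentiles 2.55 and 94.5, inside the central 95%), adipocyte markers -0.21 and 0.22 over 6 (percentiles 1.65 and 99.9; 0.11 over the 7 measured on the light-touch array), and connective tissue markers -0.06 and 0.20 over 10 (Postn 0.40 and 0.30; percentiles 20.4 and 100). With the other tissues' median subtracted, the adipocyte and heat shock medians over no stimulus turned to 0.03 and 0.07. Mgat3 (2.14) and Sec14l2 (2.04) were higher over light touch, with 0.02 and 0.13 over no stimulus. Among the genes that the naming rule left after those for both arrays, Cage1 was the lowest over light touch (-0.99, and -0.51 over no stimulus).

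Genes that differed the same way from both comparators were fewer. The stress-induced phosphatase gene Dusp1 was 1.80-fold and 2.12-fold higher (0.85 and 1.08), the receptor gene Gpr83 had 1.59 and 0.80, the Wnt inhibitor gene Wif1 had 1.37 and 0.66, and Reg3b had 0.71 and 0.74. Glucocorticoid-responsive genes had medians of 0.31 and 0.11 over 16 genes (percentiles 100 and 99.7), 12 of them above 0 on both arrays, with Fkbp5 at 0.68 and 0.44 and Tsc22d3 at 0.33 and 0.18. Lower on both arrays were Tfrc, the transferrin receptor gene, with all 5 probes between -1.13 and -0.60 (medians -0.82 and -0.92), Fetub (-2.56 and -1.16), Plxnb3 (-1.85 and -1.21), Plekhs1 (-1.57 and -1.07) and the protease gene Furin (-1.13 and -0.79). A pair of immunoglobulin kappa segments, Igkv28 (-2.35 and -1.10) and Igkv2-112l2 (-1.80 and -0.73), were lower as well, with the reserve that such segments are alike in sequence. Unfolded protein response genes had medians of -0.17 and -0.16 (percentiles 0.34 and 0.01), with 11 of 15 below 0 on both arrays, among them the chaperone gene Hspa5 (-0.51 and -0.37) and Chac1 (-0.57 and -0.47). Prpf31 again had -1.23 on both arrays, which became 0.23 after the median of the other tissues was subtracted, and Kcnh4, Cldn19, Vsir, Myoc and 4 olfactory receptor genes, whose family has many close relatives, completed the lists of genes higher or lower on both arrays.

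Clock genes in the salivary glands had medians near 0 (-0.07 and 0.00 over 13 genes) because members went both ways: Nr1d1, which encodes the repressor REV-ERB alpha, had 1.07 and 0.65, Dbp 0.65 and 0.53, and Nr1d2 0.54 and 0.50, whereas the activator gene Bmal1 had -0.67 and -0.65. T cell markers had medians of 0.12 and 0.05 (Cd28 0.52 and 0.57) and B cell markers 0.13 and 0.12 (Fcer2 0.59 and 0.15). Medians were -0.09 and -0.12 for erythroid markers (Hbb -0.64 and -0.30; -0.18 over the 12 measured over no stimulus), -0.04 and 0.02 for interferon-stimulated genes (Oasl -0.57 and -0.44), -0.12 and 0.05 for heat shock genes (Hsph1 -0.61 and -0.12), and 0.04 and 0.08 for skeletal muscle markers (Eno3 0.49 and 0.52). They were -0.00 and -0.04 for autonomic receptors (Adrb1 0.55 and -0.35) and 0.01 and -0.03 for MHC class II. Medians were -0.05 and 0.02 for ribosomal protein genes, -0.01 and -0.06 for oxidative phosphorylation and -0.04 and 0.02 for reference genes.

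Counted by size, 98 salivary genes were 2-fold or more higher and 107 lower in tickled than in the no-stimulus sample, against 20 higher and 7 lower than in the light-touch sample. Tickled glands lay 2-fold apart from both comparators for 6 genes, 1 higher and 5 lower; the lower ones were Prpf31, Plxnb3, Fetub, Igkv28 and Plekhs1, and the higher one, named here after its values were seen, was the proline-rich protein gene Prpmp5 (1.51 and 1.17). Its probes disagree: the 1 probe valued on both arrays had 1.51 and -0.10, and the other had 2.43 over light touch alone. No-stimulus glands lay apart from both others for 140 genes, 74 of them higher and 66 lower in that sample, and light-touch glands for 13. Exchangeable samples gave a mean of 38.9 and at most 58 in simulation. Their values were drawn from both salivary arrays together, with variances of 0.116 over no stimulus and 0.034 over light touch. The spread of the no-stimulus array thus enters every simulated sample, and these counts are no benchmark free of effects. Of the salivary lists, 2 put the tickled sample apart, 8 the no-stimulus sample and 3 the light-touch sample. Across 10344 genes the 2 arrays correlated with r = 0.35 and rho = 0.49 (covariance 0.022). Exchangeable samples gave r = 0.50, rho = 0.47 and a covariance of 0.037 in simulation. The observed r lay below and rho slightly above the simulated value. The simulated r is fixed near 0.50 by giving all samples the same spread, whereas these 2 arrays differ in variance.

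**Figure D3:**
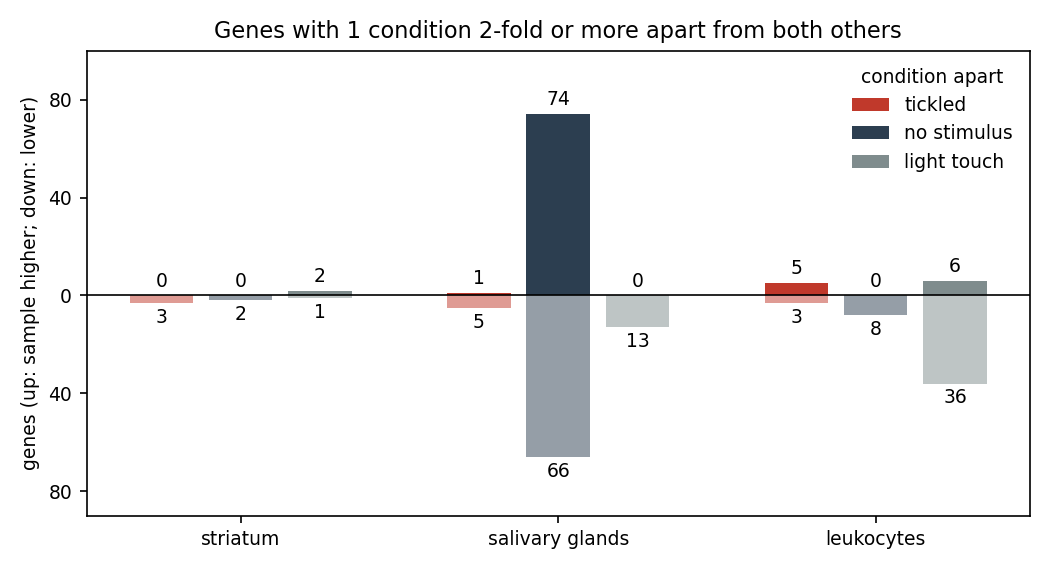
Bars count genes for which the tickled, no-stimulus or light-touch sample lay 2-fold or more above (up) or below (down) both other samples of its tissue, with light touch against no stimulus taken as the difference of the 2 arrays. The no-stimulus salivary sample stood apart for 74 genes higher and 66 lower, and the tickled samples for 3 genes in striatum, 6 in salivary glands and 8 in leukocytes.

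In peripheral leukocytes, the tickled sample was compared for blood cell genes. Myeloid genes were higher in tickled than in the no-stimulus sample: neutrophil markers had a median of 0.70 over 8 genes (percentile 100), with 5 of them 1.5-fold or more higher, and monocyte markers a median of 0.35 over 7 (percentile 99.6). Over light touch these medians were 0.22 and 0.07 (percentiles 89.8 and 62.9). The neutrophil median over no stimulus was 0.38 over 6 genes with the other tissues' median subtracted, a change that mixes loss of genes with the subtraction. Csf3r, the receptor of the neutrophil growth factor G-CSF, was higher over both comparators (0.82 and 0.78), and Padi4, an enzyme of neutrophils, had 0.93 and 0.50, whereas the alarmin gene S100a9 had 0.82 and -0.32. Slpi, a secreted protease inhibitor gene, was 4.87-fold higher over no stimulus (2.28) and had 0.22 over light touch, and Fn1 (fibronectin) had 1.56 and 0.10.

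Platelet markers went apart between the arrays, with a median of 0.30 over no stimulus (percentile 98.7) and -0.64 over light touch (percentile 0.01), the latter becoming -0.04 over 5 genes with the other tissues' median subtracted. Clec1b had 0.14 and -1.13, Gp5 0.30 and -0.75, and the chemokine gene Pf4 0.28 and -0.64. Interferon-stimulated genes had medians of 0.21 and 0.13 over 15 genes (percentiles 99.2 and 86.4), and 2 were 1.5-fold higher on both arrays, Bst2 (0.69 and 1.19) and Ifit3 (0.63 and 0.59), with Isg15 at 0.86 and 0.54 and Oas1a at 0.74 and 0.55. Among inflammatory genes Il1rn, the interleukin 1 receptor antagonist gene, had 0.78 and 0.85 (list medians 0.23 and 0.32 over 7 genes, percentiles 96.2 and 96.6; 0.12 over the 10 measured on the light-touch array). T cell markers had medians of -0.18 and -0.02 (percentiles 3.82 and 34.0), with Il7r at -0.49 and -0.39, and natural killer and cytotoxic markers -0.01 and 0.01, with Klrd1 at -0.54 and -0.44. B cell markers had 0.25 and -0.06 (Fcrla 0.26 and 0.67), MHC class II genes 0.18 and 0.19 (RT1-Ba 0.22 and 0.25), and erythroid markers 0.13 and -0.06 (Car1 0.16 and 0.20). Of the eosinophil and basophil markers only Prg2 (0.51 and 0.59) and Hdc (0.77 and -0.34) were measured on both arrays.

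Among housekeeping and stress lists in leukocytes, cell cycle genes had medians of 0.25 and 0.11 (Cdk1 0.69 and 0.41; percentiles 99.0 and 77.5) and ribosomal protein genes -0.14 and 0.02 (Rps24 -0.54 and -0.80; percentiles 1.31 and 66.8). Medians were -0.08 and -0.10 for oxidative phosphorylation genes (Cox6c -0.52 and -0.35), -0.13 and -0.33 for heat shock genes (Dnaja1 -0.57 and -0.52; percentiles 19.0 and 3.48), 0.02 and -0.07 for glucocorticoid-responsive genes (Klf9 -0.48 and -0.42) and 0.05 and -0.13 for reference genes (Actb 0.27 and -0.38). The glucocorticoid median over no stimulus was -0.08 over all 10 genes measured there, the opposite sign. Clock genes valued on both arrays numbered 3, with medians of -0.24 and -0.04 and Bmal1 at -0.73 and -0.67; over the 4 measured on the light-touch array the median was -0.22.

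The leukocyte genes furthest from both comparators mostly rested on 1 probe. Higher were Phf7 (4.00-fold and 3.48-fold), the haemoglobin gene Hba-a3 (1.34 and 2.63), whose paralogs are near-identical, Tjap1 (1.16 and 1.58), Mfsd10 (1.14 and 1.70), the transcription factor gene Zeb2 (1.03 and 0.97), Zfp106 (1.39 and 0.93) and Tasp1 (0.90 and 1.91). Lower were the aquaporin gene Aqp11 (-1.51 and -1.48), Zc3h8 (-1.07 and -1.05), the splicing regulator gene Ptbp2 (-1.05 and -1.11), Ube4b (-0.92 and -0.90), Nrbf2 (-0.87 and -1.19) and Trib2 (-0.78 and -0.88). On 1 array, Tppp3 was higher over no stimulus (1.87, and 0.13 over light touch), as was the lipid transfer protein gene Pltp (1.42 and -0.67), and Giot1 (-1.22) and Trat1 (-1.02) were lower; Atxn2l (1.86) and Marcksl1 (1.69) were higher over light touch with 0.19 and 0.13 over no stimulus, and Stard3nl (-1.80) and Txlng (-1.29) were lower.

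At 2-fold, 24 leukocyte genes were higher and 9 lower over no stimulus, and 89 were higher and 17 lower over light touch. With both arrays scaled to 1 spread, 45 were higher and 16 lower over no stimulus, and 56 higher and 10 lower over light touch. Tickled leukocytes lay apart from both comparators for 8 genes, 5 higher and 3 lower, the no-stimulus sample for 8 and the light-touch sample for 42, of which 36 were lower in it. Exchangeable samples, with values drawn from both leukocyte arrays together, gave a mean of 10.5 and at most 22 in simulation. Of the leukocyte lists, 0 put the tickled sample apart, 3 the no-stimulus sample and 1 the light-touch sample. The 2 arrays correlated with r = 0.50 and rho = 0.51 across 5812 genes (covariance 0.061), next to a simulated r of 0.50, rho of 0.48 and covariance of 0.063. The simulated r and covariance again follow from the construction.

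Between tissues, the tickled over comparator ratios were weakly correlated. The 4 pairs of striatal and salivary arrays correlated across genes with r from 0.14 to 0.23 and rho from 0.23 to 0.27. Their covariances were 0.006 to 0.011, against 0.018 between the 2 striatal arrays. The gene sets and the spreads of the arrays differ, so the share of the striatal covariance common to both tissues was not determined. Pairs with a leukocyte array had r from 0.04 to 0.09 and rho from 0.03 to 0.10. Prpf31 was the 1 gene 2-fold the same way in both arrays of 2 tissues, lower in tickled striatum and salivary glands, where independent lists would share 0.0004 genes. At 1.5-fold, Bmal1 was lower in both arrays of salivary glands and leukocytes, against 0.0485 genes for independent lists. Tickled RNA carried the same dye on all 6 arrays, so a probe with a dye bias has the same sign in each tissue.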

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

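No explanation was tested for the results given here, and the 8-fold limit for features without a gene name was chosen after the values were seen.

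Igkv2-112l2, an immunoglobulin kappa segment, went opposite ways in different tissues. Its log2 ratios were -1.80 over no stimulus and -0.73 over light touch in salivary glands, and 0.59 and 0.81 in leukocytes. The difference between tissues was not tested, and probes of such segments can read their relatives.

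Features without a gene name take no part in the comparisons. Among those valued on both arrays, 3 were 8-fold or more apart the same way on both. Feature 39322 had -3.16 and -3.25 in striatum, and in salivary glands feature 2903 had 5.20 and 4.57 and feature 32921 had 4.52 and 6.90. None of the 3 had a value in the other tissues. In all, 10536 unnamed features in striatum, 9551 in salivary glands and 4258 in leukocytes had values on both arrays, of which 1, 7 and 4 were 2-fold higher on both and 2, 12 and 1 lower.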

How the results depend on the processing

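The natural log reading was chosen after the values were seen; the other alternatives were planned. No paired analysis was possible because each comparison has 1 array. Counts below are for striatum, salivary glands and leukocytes in that order, given as no-stimulus array, light-touch array and both arrays the same way.

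Centring the arrays and the mean over probes moved no count, correlation or list result that answers a comparison beyond 1.5 times its value or its probe error. The filter on values of exactly 0 removed nothing and so tests nothing. Over all settings, of the list medians that answer no comparison alone, 849 kept their value within the error, 54 moved and 11 reversed. Of the values of named genes, 4554 stayed within the error, 525 moved and 2 reversed. The kept totals include 125 list medians and 732 gene values from the filter that removed nothing. They also include 685 gene values from leaving out genes alike in the other tissues and 164 from keeping agreeing probes. Such settings only drop genes, so the value of a remaining gene cannot change. The kept totals are therefore no measure of robustness.

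The counts follow the fold limit by construction. At 2-fold they were 15, 18 and 3, then 205, 27 and 6, then 33, 106 and 8. At 1.5-fold they were 139, 147 and 46, then 597, 174 and 51, then 386, 813 and 110. At 3-fold they were 1, 1 and 0, then 66, 5 and 0, then 3, 12 and 1. Read as natural logs they were 75, 82 and 30, then 427, 88 and 19, then 181, 481 and 40.

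Scaling both arrays of a tissue to 1 spread gave 8 and 52 genes in striatum, 43 on the salivary light-touch array, and 61 and 66 in leukocytes. It moved the cortical marker median over light touch from -0.61 to -0.765 and the kallikrein median over no stimulus from 2.15 to 1.874. With the smallest probe these were -0.487 and 1.879, and 1 salivary list instead of 2 lay outside the central 95% on both arrays. These changes follow from the settings. Scaling multiplies all values of an array by the same factor, and the smallest probe brings gene values closer to no difference.

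Keeping genes with 2 or more agreeing probes leaves fewer genes: 1140, 1277 and 463 on both arrays. The counts were then 3, 1 and 1, then 21, 2 and 0, then 2, 3 and 0, the same as the deposited values give over those genes. The correlations were 0.714, 0.537 and 0.574, again the same as the deposited values give over those genes. Of the striatal lists, 1 instead of 7 lay outside, but lists left with fewer than 3 genes were not counted. The striatal neurotrophic list reversed to -0.551 and -0.578 over its 3 remaining members.

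Subtracting the other tissues' median takes the same number from both arrays, which adds a shared part to both. The correlations were 0.742, 0.502 and 0.529, against 0.544, 0.388 and 0.503 for deposited values over the same genes. Striatum had 31, 34 and 14 genes, the last with 10 higher and 4 lower, and 4 lists outside. The cortical median over light touch became -0.322 over 6 markers and the granular duct median over no stimulus 0.052 over 4. The neutrophil median over no stimulus became 0.38 over 6 and the platelet median over light touch -0.04 over 5. Where genes without enough values in the other tissues fell out, such a change mixes their loss with the subtraction. Unsubtracted medians over only the genes left were not computed. In striatum these list medians reversed: neurotrophic -0.023, choroid plexus -0.021, erythroid 0.029, heat shock 0.028 and oxidative phosphorylation 0.008 over light touch, and thalamus and septum -0.147 and glucocorticoid -0.083 over no stimulus. In salivary glands, adipocyte 0.03 and heat shock 0.074 reversed over no stimulus, and Prpf31 became 0.235 and 0.229 because its striatal values are lower still. The cause of the other reversals was not tested. Leaving out genes alike in the other tissues gave a leukocyte correlation of 0.526, the value that the 4900 genes left have as deposited. Signal over background was not used here, so its effect on small ratios is not known.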

Other observations

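All 6 tests of explanations in this part were chosen after the results were seen.

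The kallikrein median over no stimulus was 2.15 in salivary glands. A dye bias of the probes is argued against, since the light-touch array with the same dyes gave -0.19, where at least 1.075 would be needed. Another mix of glands in the no-stimulus sample is a candidate explanation: the mucous acinar markers, a cell type of other glands, had a median of -1.30 over no stimulus, from 3 genes. A response of the ducts to handling, shared by tickling and light touch, was not tested and stays open, as do signal shared between the kallikrein paralogs and a different tickled extract on each array.

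The cortical marker medians in striatum were -0.57 and -0.61. Dye bias is not excluded: the markers had a median of 0.11 over the arrays of the other tissues, but 2 of 6 measured there, Neurod6 and Nrn1, lay below the bound of -0.28, and Tbr1 had no value there. Less cortical tissue in the tickled sample requires that the medium spiny markers are not lower to a like extent, and their lower median was -0.10. Dye bias of the cortical probes or lower expression within cortical neurons would also meet this, so the test does not tell them apart. The requirement is also lenient, since a median just above -0.28 would pass it. Of the 16 medium spiny markers, 3 lay above 0 over no stimulus (percentile 6.93) and 8 over light touch (percentile 50.5). They were thus not higher as a set, which a smaller cortical share could make them. The cortical markers Lamp5, Nrgn and Rtn4rl2 did not share the decrease. Lower expression within cortical or striatal neurons after tickling was not tested and stays open.

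Clock genes of opposite phase lay apart in tickled salivary glands, where the group that peaks with Nr1d1 minus the group that peaks with Bmal1 was 0.70 over no stimulus and 0.74 over light touch. Dye bias is not excluded: turned to the salivary sign, the same 11 genes had a median of 0.12 in the other tissues, under the bound of 0.24, but 3 of them reached it. Another clock phase at collection cannot be told apart from a local difference: the same measure was 0.21 and 0.36 on the striatal arrays, and the smaller value lies between the bounds set for either reading. On the leukocyte arrays it was 0.19 and 0.25, but from only 2 genes of the Bmal1 group and 1 of the other. A shift of phase by the stimulation was not tested.

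Some lists fixed for other tissues also lay outside the central 95% on both arrays. Unfolded protein response genes had medians of -0.24 and -0.14 in striatum over 14 genes, and monocyte markers 0.16 and 0.15 over 8. In salivary glands, inflammatory genes had 0.22 and 0.15 over 11 genes, and microglia markers, which macrophages share, 0.37 and 0.10 over 10. Eosinophil and basophil markers had 0.42 and 0.17 over 4 genes, but -0.18 over the 5 measured on the light-touch array, and oligodendrocyte markers had 0.23 and 0.20 over 5, but 0.02 over the 9 measured there.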
